A study of Pinus sylvestris with 30 samples.

How the data were processed

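RNA was measured in 5 tissues of 6 unrelated Scots pine trees, 1 library per tissue and tree, 30 libraries in all. Needle, phloem and vegetative bud were taken from the tree itself. Embryo and megagametophyte, the haploid maternal storage tissue of a conifer seed, were dissected from seeds of the same 6 mother trees after 48 h of germination in moisture and light. Per the labels' protocols, mRNA of the seed tissues was taken directly from the lysate on oligo(dT) beads, whereas vegetative tissues went through a total RNA kit before poly(A) capture. The isolation method therefore coincides with seed against vegetative tissue throughout. All libraries were strand-specific and paired-end, and were sequenced in 5 runs of 6 to 12 pooled libraries, per the labels' protocols. The run of each library is not given in the sources used here, so no comparison within runs was made.

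The authors deposited 2 tables with the same 715398 identifiers. The identifiers have the form that the Trinity assembler gives at gene level, and are called assembled genes here. They fall into 355099 groups that share the first part of the identifier. Several assembled genes can therefore be alleles, paralogues or fragments of 1 gene, and reads of close copies can be split between them. Abundance was estimated with Salmon 0.9.1, per the submitters' processing notes. The transcriptome used as reference, the trimming, the strand setting and the rule that grouped transcripts into genes are not given in the sources used here. The first deposited table holds TPM, an abundance corrected for transcript length and library total, with no scaling between libraries, and its columns sum to between 76.4% and 89.1% of the total that TPM fixes for a whole library, so the remainder of each library lies outside the table. By tissue, the columns held 79.4% ± 1.61 in embryo (SD, n = 6), 82.0% ± 1.25 in megagametophyte, 84.1% ± 0.439 in vegetative bud, 85.1% ± 0.535 in phloem and 88.1% ± 0.634 in needle. The part outside the table thus differed by tissue, and how this bears on the counts was not tested. Shares of a total given below are shares of what the table holds. The second deposited table is a signal without a fixed total: each of its columns is the TPM column multiplied by 1 factor per library, between 0.790 and 1.50, and its file name points to TMM scaling. It is called scaled TPM here. TPM keeps no read depth, so the depth behind each value is unknown and no counting interval or detection floor is given. The number of replicates sets the precision.

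Columns were matched to libraries by the library names in the labels. In 5 columns the name carries an additional number after the library name, and each was matched to the only library it fits. No column was left unmapped. The files do not pair identifiers with gene names, and no annotation was used here, so assembled genes are given by identifier. The 12 lists of marker and pathway genes that had been fixed beforehand could not be matched, and their tests were not run.

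Assembled genes with a scaled TPM of at least 1 in at least 6 of the 30 libraries were kept, which left 76648. Of the remaining 638750, 15782 were listed at 0 in every library. The kept assembled genes held between 83.7% and 95.3% of each library's scaled total. Values were transformed to log2(scaled TPM + 1), so a difference understates the change of assembled genes with low values. Tissue means were fitted to all 30 libraries together with limma 3.58.1 in R 4.3.3 (moderated test, eBayes with a mean trend), and p-values were adjusted by the Benjamini-Hochberg method over the kept assembled genes. A difference was called at an adjusted p under 0.05 and a log2 difference of at least 1. An assembled gene was called preferential in a tissue when it was higher there than in each of the other 4. It was called specific when the tau index over the 5 tissue means was at least 0.85, the tissue had the highest mean, and at least 5 of its 6 libraries reached 1. Tau runs from 0 for equal means to 1 for expression in a single tissue. It was called detected in a tissue at a scaled TPM of at least 1 in at least 5 of the 6 libraries. The tree effect was limma's moderated F over tree, in a model of tissue and tree on the 18 vegetative libraries, at an adjusted p under 0.05. Measures with 1 value per library were compared between tissues with 2-sided exact permutation tests, adjusted over 20 tests, and again paired by tree with exact sign-flip tests, which were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used besides R.

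The tests, thresholds and the rule for named assembled genes were fixed before the data were examined. For each comparison and direction, that rule took the 2 called assembled genes with the largest log2 difference whose libraries did not overlap between the groups and whose mean in the higher group was at least 10. For a tissue against the other 4, the smallest of the 4 differences was used, and the adjusted p given is the highest of the 4.

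Same-tree libraries were checked for joint deviations. After subtraction of tissue means, the correlation across assembled genes between 2 libraries of 1 tree lay between 0.0622 and 0.524 in 60 pairs. Of these, 4 pairs, all of embryo and needle, were under 0.1. In 116 of 120 comparisons a library correlated best with the library of its own tree. The labels state the shared tree, so the libraries are paired, and a fit with tree as a block was run as an alternative. The highest correlation of log2 values between 2 libraries was 0.844, and none was deposited under 2 names.

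The procedure was tested on simulated data made from the real means, with independent normal noise and no deviations shared within a tree. Changes between tissues were placed only on assembled genes above a limit on the mean. For needle against vegetative bud, it called 36%, 76%, 80% and 92% of 50 assembled genes each, changed by a log2 difference of 1.5, 2, 3 and 4, and 12 unchanged ones among the 76648. Differences of 1.5 and 3 raised needle, whereas those of 2 and 4 raised the other tissues, so size and direction coincided. For preference in needle it called 49 of 100 assembled genes raised by 1.5 or 3, and 0 unchanged ones. For the tree effect every mean was first raised by 3 log2 units, so the rate at the real levels is not given. There it called 77 of 200 changed by a log2 difference of 3 in a single tree, and 2 unchanged ones. Alternatives covered the pseudocount, the filter, the scaling, the thresholds, the libraries in the fit, the tree block, robust eBayes and leaving out each tree in turn.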

Results

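The series asked which genes of Scots pine (Pinus sylvestris) are expressed preferentially or specifically in 1 of 5 tissues, and used 6 unrelated adult trees from a natural forest so that tissue patterns could be read across genotypes. Embryo, megagametophyte, needle, phloem and vegetative bud were each represented by 6 libraries, 1 per tree. The trees are numbered 251, 320, 397, 443, 463 and 485. Between 41294 and 77651 assembled genes per library (median 56418) reached a scaled TPM of 1. Read depth is unknown from these values.

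Tissue separated the libraries along the first 4 principal components. The first component, with 24.1% of the variance, placed the 12 seed libraries on one side (scores −211.6 to −161.7) and the 18 vegetative libraries on the other (19.3 to 195.9), with vegetative bud closest to the seed tissues. The second component, with 17.0%, set needle (202.5 to 239.2) apart from phloem and vegetative bud (−145.6 to −128.3). The third component, with 10.1%, set vegetative bud apart from phloem, and component 4, with 6.13%, set embryo apart from megagametophyte. Mean Pearson correlations across assembled genes, which are not independent replicates, were 0.800 within needle, 0.788 within phloem, 0.778 within vegetative bud, 0.774 within embryo and 0.705 within megagametophyte. Between tissues they were highest for embryo with megagametophyte and for phloem with vegetative bud (0.609 for both), followed by embryo with vegetative bud (0.553). They were lowest for embryo with needle (0.410). Components 5 and 6, with 4.82% and 4.19%, did not follow tissue alone. On component 6 the 5 libraries of tree 251 had scores of 63.98 to 150.2, and those of tree 320 scores of 25.21 to 78.37. The libraries of the other 4 trees lay between −81.86 and 12.83.

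**Figure D1:**
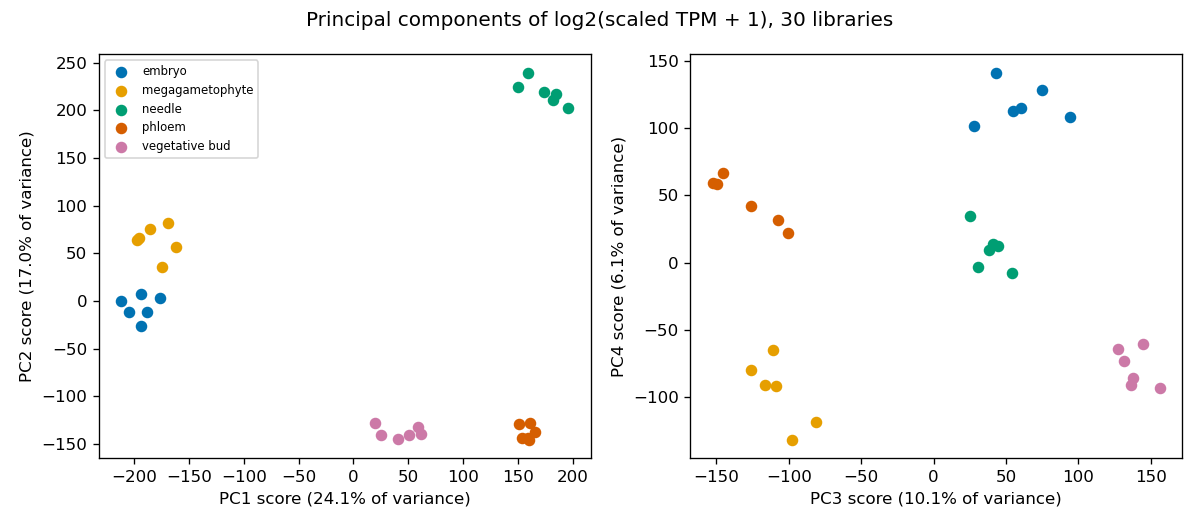
Scores of the 30 libraries on principal components 1 and 2 (left) and 3 and 4 (right) of log2(scaled TPM + 1), with the percentage of variance on each axis and 1 point per library, coloured by tissue. Seed libraries lie at −161.7 or lower on component 1, vegetative libraries at 19.3 or higher, and needle libraries at 202.5 or higher on component 2.

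Counting assembled genes detected in at least 5 of 6 libraries, vegetative bud had the most and megagametophyte the fewest: 32100 assembled genes were detected in vegetative bud, 29430 in needle, 29205 in phloem, 27694 in embryo and 23140 in megagametophyte. Of the 51767 detected in any tissue, 13450 (26.0%) were detected in all 5 and 18078 (34.9%) in 1 tissue. Needle had the most detected there alone (5053), then vegetative bud (3959), phloem (3468), embryo (3397) and megagametophyte (2201). The number per library reaching 1 ordered the tissues differently, with means of 61238 ± 8213 in vegetative bud (SD, n = 6), 59632 ± 4146 in megagametophyte, 55949 ± 4726 in needle, 55255 ± 4454 in phloem and 52593 ± 6033 in embryo. No pair of tissues passed adjustment over 20 tests. The smallest unpaired exact permutation p was 0.0130, for embryo against vegetative bud (adjusted 0.0520). Paired by tree, megagametophyte exceeded embryo in 6 of 6 trees, by 7038 ± 3714 (SD, n = 6), with an exact sign-flip permutation p of 0.03125, the smallest that 6 trees allow (adjusted 0.125). The vegetative bud library of tree 397, the megagametophyte library of tree 320 and the needle library of tree 463 stood apart, with 19136, 19138 and 14669 assembled genes that reached 1 in that library alone, against a median of 5677 over the 30 libraries.

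Needle expression was concentrated in few transcripts. The 100 most abundant assembled genes held 31.1% ± 3.86 (SD, n = 6) of the needle total, against 17.4% ± 3.98 in phloem, 16.7% ± 3.48 in megagametophyte, 13.1% ± 3.67 in embryo and 12.9% ± 2.20 in vegetative bud. The difference between needle and each other tissue had an exact permutation p of 0.00216 (adjusted 0.0108, n = 6 per tissue), with every needle library above every other library. Paired by tree, needle was higher in 6 of 6 trees in each case (exact sign-flip permutation p = 0.03125, the smallest possible, adjusted 0.125). The single most abundant assembled gene held 3.36% ± 0.440 of the needle total. The authors' scaling factor was also highest in needle, 1.31 ± 0.108, against tissue means of 0.867 to 1.05 elsewhere.

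Of the 76648 assembled genes tested, 14223 (18.6%) were preferential in 1 tissue. Needle had 5314, phloem 3515, vegetative bud 2544, embryo 1490 and megagametophyte 1360. The specific sets, which use tau and no test, held 2579 in needle, 1502 in vegetative bud, 1403 in phloem, 866 in embryo and 695 in megagametophyte. With a pseudocount of 0.1, those of vegetative bud, phloem and megagametophyte were smaller by a factor of over 1.5. Preferential assembled genes held 47.5% ± 2.7 (SD, n = 6) of the needle total, 23.9% ± 5.26 of the phloem total, 12.6% ± 2.64 of the megagametophyte total, 12.6% ± 2.6 of the vegetative bud total and 9.06% ± 1.67 of the embryo total. Without the 3 libraries that stood apart, the preferential counts were 5337 in needle, 3340 in phloem, 2550 in vegetative bud, 1457 in embryo and 1394 in megagametophyte. With a minimum log2 difference of 2 they were 2825, 1545, 1182, 667 and 652 in that order of tissues. The order of embryo and megagametophyte turned with no filter (1477 and 1608), after quantile normalization (1792 and 1952) and with a pseudocount of 5 (820 and 893), and that of their specific sets turned without the 3 libraries (889 and 991).

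**Figure D2:**
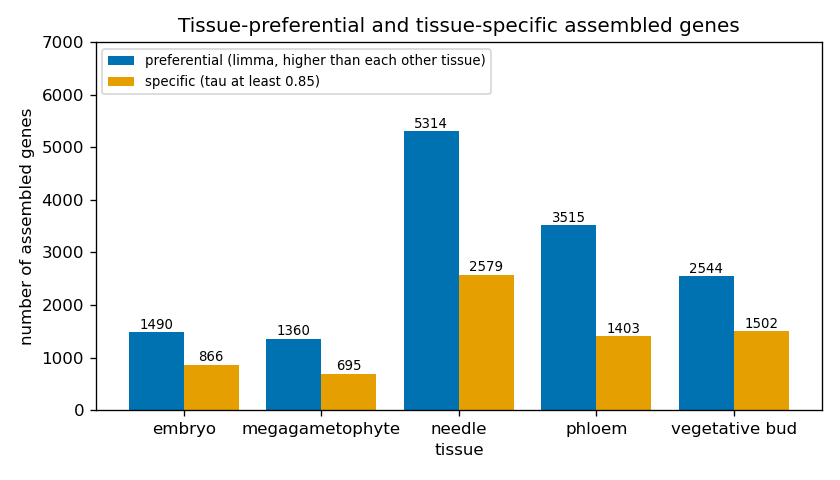
Number of assembled genes called preferential (blue, limma, higher than in each other tissue) and specific (orange, tau of at least 0.85) in each tissue. Needle has the most of both, 5314 and 2579; embryo, with 1490 and 866, and megagametophyte, with 1360 and 695, have the fewest, and their order turns under alternative settings.

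In embryo, the leading preferential assembled genes were close to absent elsewhere. TRINITY_DN205293_c38_g2 reached 1255 ± 942.5 scaled TPM (SD, n = 6) in embryo, lay between 0 and 4.69 in megagametophyte, and was listed at 0 in all 18 vegetative libraries. TRINITY_DN201416_c6_g1 reached 779.2 ± 438.9 in embryo and at most 4.79 in any library of another tissue. Their smallest log2 differences were 8.88 (SE 0.44, adjusted p = 2.42e-15) and 8.35 (SE 0.31, adjusted p = 3.21e-18), both against megagametophyte. Of the 1490 preferential assembled genes, 936 were detected in embryo alone and 715 were also specific, and their median smallest log2 difference was 1.84.

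In megagametophyte, TRINITY_DN203682_c11_g1 reached 2089 ± 1101 scaled TPM (SD, n = 6) and TRINITY_DN205676_c17_g1 reached 2943 ± 1364. In embryo the first lay between 0.841 and 5.77 and the second between 0.843 and 63.3. Both were listed at 0 in the 6 vegetative bud libraries and were at most 1.19 in needle and phloem. Their smallest log2 differences were 9.10 (SE 0.34, adjusted p = 2.76e-18) and 8.76 (SE 0.54, adjusted p = 2.17e-13). Of the 1360 preferential assembled genes, 722 were detected in megagametophyte alone and 515 were also specific. Their median smallest log2 difference was 1.94.

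Needle had the largest differences of the 5 tissues among the named assembled genes. TRINITY_DN193215_c3_g4 reached 9756 ± 3899 scaled TPM (SD, n = 6) and TRINITY_DN177486_c9_g5 reached 7952 ± 3318. Both were listed at 0 in megagametophyte, were at most 0.182 in embryo and did not exceed 3.29 in phloem or vegetative bud. Their smallest log2 differences were 12.42 (SE 0.25, adjusted p = 1.58e-24) and 12.10 (SE 0.30, adjusted p = 1.92e-22). Of the 5314 preferential assembled genes, 2838 were detected in needle alone and 2109 were also specific, and 1362 had a smallest log2 difference of at least 3.

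In phloem, TRINITY_DN194839_c6_g5 reached 714.0 ± 407.3 scaled TPM (SD, n = 6) and TRINITY_DN191341_c3_g1 reached 552.9 ± 238.9. Both were listed at 0 in every embryo and needle library. The first reached 0.822 in 1 megagametophyte library and 0.870 in 1 vegetative bud library, and the second 0.627 in 1 vegetative bud library. Their smallest log2 differences were 9.13 (SE 0.28, adjusted p = 2.76e-20) and 8.88 (SE 0.22, adjusted p = 1.72e-22). Of the 3515 preferential assembled genes, 1649 were detected in phloem alone and 1220 were also specific.

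In vegetative bud, TRINITY_DN170697_c0_g2 reached 313.4 ± 246.9 scaled TPM (SD, n = 6) and was listed at 0 in all 24 libraries of the other tissues. TRINITY_DN178235_c0_g3 reached 454.0 ± 250.1, with 0.863 to 2.69 in phloem, 0 to 5.75 in needle and at most 0.606 in the seed tissues. Their smallest log2 differences were 7.89 (SE 0.33, adjusted p = 2.61e-17) and 7.14 (SE 0.38, adjusted p = 6.48e-15). Of the 2544 preferential assembled genes, 1553 were detected in vegetative bud alone and 1225 were also specific.

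**Figure D3:**
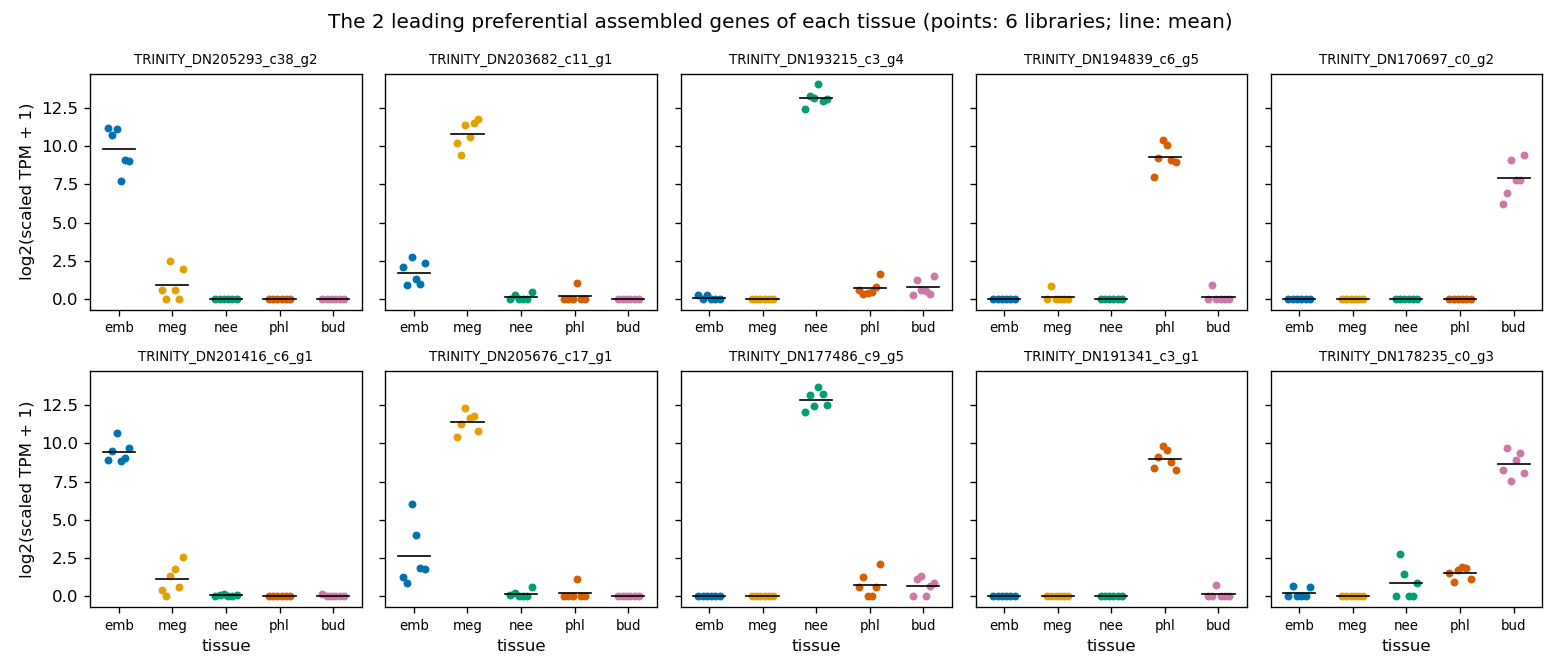
Values of the 2 leading preferential assembled genes of each tissue, as log2(scaled TPM + 1) on the vertical axis and tissue on the horizontal axis (emb, embryo; meg, megagametophyte; nee, needle; phl, phloem; bud, vegetative bud). Points are the 6 libraries of a tissue and lines their means; in each panel the 6 libraries of the preferred tissue lie above the other 24.

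Seed and vegetative tissues differed in 21094 assembled genes (27.5%), of which 6596 were higher in seed and 14498 higher in vegetative tissue. Seed here is the mean of embryo and megagametophyte, and vegetative tissue the mean of needle, phloem and vegetative bud. A difference in a single tissue can therefore give a call. Some calls had no overlap between classes and a mean of at least 10 in the higher class. They were 225 higher in seed and 847 higher in vegetative tissue. TRINITY_DN193705_c6_g1 averaged 1060 ± 594.7 scaled TPM in embryo and 1852 ± 1493 in megagametophyte (SD, n = 6 each), and was at most 1.63 in any vegetative library. TRINITY_DN202005_c15_g1 averaged 851.3 ± 634.4 and 1703 ± 1466, with at most 1.59 in any vegetative library. Their log2 differences were 9.62 (SE 0.33, adjusted p = 2.32e-19) and 9.38 (SE 0.37, adjusted p = 4.23e-18). In the other direction, TRINITY_DN177757_c3_g6 averaged 8458 ± 6158 in phloem, 2428 ± 2418 in needle and 93.4 ± 56.4 in vegetative bud, and did not exceed 5.49 in a seed library (log2 difference 9.36, SE 0.39, adjusted p = 1.57e-17). TRINITY_DN178765_c1_g5 had the same order, with 2566 ± 1645 in phloem, 1113 ± 424.3 in needle and 46.0 ± 34.1 in vegetative bud, and at most 0.235 in a seed library (log2 difference 8.66, SE 0.29, adjusted p = 1.08e-19). The balance of directions depended on the scaling: 31.3% of the calls were higher in seed, against 41.4% in TPM without scaling between libraries and 46.4% after quantile normalization, where 10177 were higher in seed. The counts also moved with the pseudocount, to 12275 higher in seed and 20757 higher in vegetative tissue at 0.1, and to 2277 and 5617 at 5. The RNA of seed and vegetative tissues was isolated by different methods, so tissue class and method coincide. Every seed library also held less of its TPM total in the table than every vegetative library (at most 83.4% against at least 83.6%).

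Within the seed, the diploid embryo and the haploid megagametophyte differed in 9585 assembled genes (12.5%), the fewest of the 10 tissue pairs. Embryo was higher for 6066 of them and megagametophyte for 3519. The assembled genes with the largest differences were those that also led the preferential sets: TRINITY_DN205293_c38_g2 and TRINITY_DN201416_c6_g1 were higher in embryo, and TRINITY_DN203682_c11_g1 and TRINITY_DN205676_c17_g1 were higher in megagametophyte, by the log2 differences of 8.88, 8.35, 9.10 and 8.76 given for them. With a pseudocount of 5 in place of 1, 2823 and 1862 assembled genes were called in the 2 directions.

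Needle and phloem differed in 18776 assembled genes (24.5%), with 9013 higher in needle and 9763 higher in phloem. The largest difference was that of TRINITY_DN193215_c3_g4 (12.47, SE 0.25, adjusted p = 1.42e-24). TRINITY_DN187845_c9_g1 reached 31740 ± 13120 scaled TPM in needle (SD, n = 6) and 6.46 ± 6.60 in phloem, a log2 difference of 12.29 (SE 0.71, adjusted p = 1.13e-14). It was not restricted to needle, with 608.5 ± 112.2 in vegetative bud, 964.5 ± 699.6 in embryo and 1029 ± 834.7 in megagametophyte. In phloem, TRINITY_DN194839_c6_g5 was listed at 0 in every needle library, and TRINITY_DN55703_c0_g1 averaged 905.7 ± 390.2 against at most 1.74 in needle (log2 difference 9.22, SE 0.43, adjusted p = 1.09e-16). The majority in phloem turned with a pseudocount of 5 (5322 higher in needle and 5286 in phloem), after quantile normalization (9025 and 8934), with no filter (9137 and 8435) and with a minimum log2 difference of 2 (4823 and 4518), while in TPM without scaling between libraries it was larger (7097 and 11433).

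Needle and vegetative bud differed in 20246 assembled genes (26.4%), the most of the 3 pairs of vegetative tissues, with 9120 higher in needle and 11126 higher in vegetative bud. TRINITY_DN193215_c3_g4 and TRINITY_DN177486_c9_g5 were again highest in needle, by log2 differences of 12.42 (SE 0.25, adjusted p = 1.58e-24) and 12.19 (SE 0.30, adjusted p = 1.92e-22). The assembled genes highest in vegetative bud relative to needle were also abundant in embryo. TRINITY_DN208987_c7_g1 averaged 1612 ± 501.8 scaled TPM in vegetative bud and 1154 ± 1023 in embryo (SD, n = 6), against at most 0.677 in needle (log2 difference to needle 10.43, SE 0.51, adjusted p = 3.87e-16). TRINITY_DN215709_c21_g3 averaged 1606 ± 381.2 in vegetative bud and 558.7 ± 532.9 in embryo, against at most 0.993 in needle (log2 difference to needle 10.26, SE 0.46, adjusted p = 4.72e-17). In the main scaling 45.1% of the calls were higher in needle, against 31.4% in TPM without scaling between libraries, 50.5% after quantile normalization (10012 higher in needle and 9802 in vegetative bud) and 50.7% with a pseudocount of 5 (5556 and 5400), so the majority depended on these choices. The median log2 difference of all assembled genes tested, needle minus vegetative bud, moved from −0.116 to −0.318 between the main scaling and TPM without scaling.

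Phloem and vegetative bud were the closest pair of vegetative tissues, with 14009 assembled genes called (18.3%), 6457 higher in phloem and 7552 higher in vegetative bud. TRINITY_DN194839_c6_g5 and TRINITY_DN191341_c3_g1 led in phloem, by log2 differences of 9.13 and 8.88. TRINITY_DN198597_c7_g1 averaged 1214 ± 380.5 scaled TPM in vegetative bud and 1053 ± 990.1 in embryo (SD, n = 6), and at most 1.59 in phloem (log2 difference to phloem 9.45, SE 0.53, adjusted p = 1.62e-14). TRINITY_DN176675_c4_g1 averaged 1771 ± 1052 in vegetative bud and 17.8 ± 16.2 in embryo, and at most 4.30 in phloem (log2 difference to phloem 9.21, SE 0.54, adjusted p = 4.37e-14). The majority in vegetative bud turned with a pseudocount of 5 (3688 higher in phloem and 3472 in vegetative bud) and was larger in TPM without scaling between libraries (5651 and 8641).

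Libraries of the same tree resembled each other beyond their tissue. The deviations of libraries from their tissue means correlated between tissues of 1 tree, on average by 0.432 for phloem with vegetative bud, 0.405 for embryo with megagametophyte, 0.355 for needle with vegetative bud and 0.346 for needle with phloem. Between seed and vegetative tissues the averages ran from 0.134 (embryo with needle) to 0.260 (megagametophyte with phloem). In the 18 vegetative libraries, 9902 assembled genes (12.9%) differed between trees after tissue was accounted for, with a median range of 2.52 log2 units between the highest and the lowest tree. Of these, 3450 had a range of at least 3. The sequencing run of each library is not given, so an effect of run or handling could not be told apart from tree here. With a filter of 5 in place of 1, 5138 assembled genes had a tree effect.

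**Figure D4:**
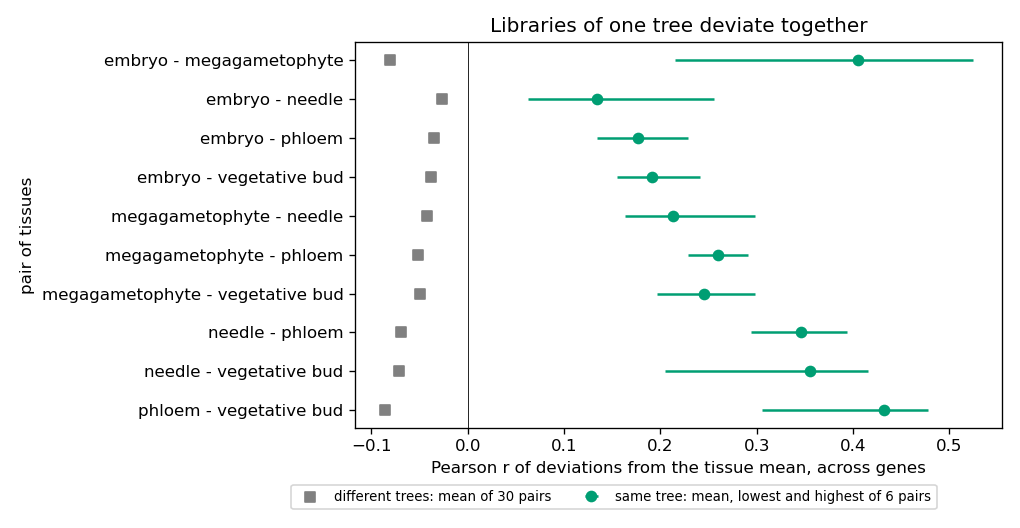
Pearson correlation across assembled genes of deviations from the tissue mean, for each pair of tissues. Green points are means over the 6 same-tree pairs of libraries, with lines from the lowest to the highest; grey squares are means over the 30 pairs of different trees, which subtraction of the tissue mean sets below 0. Same-tree means run from 0.134 to 0.432.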

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

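The comparison of embryo with megagametophyte where the mother tree lacked an assembled gene, the comparisons of that excess between both kinds of mother, the comparison of trees and the shuffling of trees for depth, the permutation of trees and the comparison across RNA isolation methods were chosen after the result was seen. The other tests here were set before their results were known.

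Some assembled genes were present or absent by tree. In 425, each tree had values of at least 5 scaled TPM in all 3 vegetative libraries or values under 0.1 in all 3, and both kinds of tree occurred. Where the mother tree had the assembled gene, 60.4% ± 5.85 (SD, n = 6 trees) reached 1 in its megagametophyte and 69.7% ± 3.81 in its embryo. Where the mother tree lacked it, 3.47% ± 1.55 did in the megagametophyte and 12.3% ± 2.68 in the embryo. Embryo exceeded megagametophyte there by 8.83 percentage points ± 1.89, in 6 of 6 trees (exact sign-flip permutation p = 0.03125, the smallest that 6 trees allow), so the 2 seed tissues differed. Assigning the megagametophyte libraries to trees in all 720 orders gave no order as large as the labelled one (56.7 percentage points between mother present and mother absent, highest other 42.4, exact permutation p = 0.0014, the smallest possible), and the same held for embryo (57.3, highest other 45.1).

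The tables argue against part of the technical causes. Carryover between libraries of a tree would leave low levels in the megagametophyte. Where values there reached 1, the median level was 1.42 times that of the 3 vegetative libraries (quartiles 0.625 and 3.08). This argues against carryover for those values. Lower values did not enter that median, so carryover below 1 stays open. An effect of sequencing run or handling was not tested, since the run of each library is not given. A single organism on a tree would bring its transcripts together only if it expressed all of them in every tissue. The 52.5% to 67.4% present in the megagametophytes therefore do not decide this cause. Of the 425, 227 were present in 1 tree, and an organism living on a tree stays open. In every pair of trees each tree had assembled genes that the other lacked (71 to 111, lowest ratio 0.732). Shallow libraries of particular trees would not give this, so it argues against them as the sole cause for the 425. Low depth otherwise stays open, since a test planned on levels (52.7% with a mean of at least 20) decides nothing where depth is unknown. Shuffling trees between the vegetative tissues left a median of 0 and at most 177 of the 425. Broader expression in the embryo also stays open: the embryo excess was 9.29 percentage points ± 3.2 where the mother had them, so it differed between both kinds of mother by −0.467 ± 3.21 points (SD, n = 6, exact permutation p = 0.78125), whereas the share ratio was larger where the mother lacked them, 3.55 against 1.15 (mean log2 ratio of ratios 1.94 ± 1.2, above 0 in 6 of 6 trees, exact permutation p = 0.03125), a measure that the high shares of the other kind of mother limit. These values hold for a seed limit of 1. At a limit of 5, embryo and megagametophyte shares were 59.1% and 54.4% where the mother had them. Where the mother lacked them, the shares at that limit were 9.66% and 0.287%. The excess was not compared between both kinds of mother at that limit. Inherited presence or absence may account for the 8.83 points, since the embryo also has genes of a pollen parent, but the number of seeds per library is not given in the sources used here. An assembled gene missing from the mother could not reach the maternal megagametophyte. Missing genes alone therefore leave the 3.47% ± 1.55 that reached 1 there unexplained. That share was 21.2% for those present in 5 trees, and 0.287% ± 0.339 at a seed limit of 5. Whether an absent assembled gene is missing, silent or another allele assembled separately was not tested.

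In 3 libraries, many assembled genes reached 1 in no other library. The vegetative bud library of tree 397 had 19136 of them and the needle library of tree 463 had 14669, each far above the other 5 libraries of its tissue, and the megagametophyte library of tree 320 had 19138. Each of the 3 also had the most assembled genes reaching 1 in its tissue, 77651, 65105 and 64281 in that order, and the first and second of these counts lay far above the other 5 of their tissue. Shallower sequencing could not be told apart from other causes: 2 of the 3 libraries listed at 0 the highest share of broadly found assembled genes in their tissue (4.85% and 9.10%), and the megagametophyte library, with 11.8%, lay below that of tree 397, with 11.9%. Transcripts of another organism could not be told apart either: the top 1% of the assembled genes above 0 in 1 library alone held at most 4.51% of their total in these libraries, but at most 15.5% in any of the 30 libraries against at least 37.0% for all assembled genes, so the measure is low in every library, and part of each library lies outside the table. No biological explanation was tested.

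The difference between seed and vegetative tissue coincides with the RNA isolation method. The 6 tissue pairs across methods had between 16660 and 24015 called assembled genes (mean 21204), and the 4 pairs within a method between 9585 and 20246 (mean 15654). The pair of embryo and vegetative bud, with 16660, crosses the methods and had fewer calls than needle and vegetative bud, with 20246, which share a method. The method and the tissue class cannot be told apart, because no tissue was isolated both ways.

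Of 86 groups of 6 libraries compared, 15 held a library far from the other 5. Chance gives about 1 in 20 for normal values, a rate that does not apply where the other 5 libraries were at 0, as for TRINITY_DN178765_c1_g5, TRINITY_DN194839_c6_g5 and TRINITY_DN191341_c3_g1. Besides the library counts given above, these were values of named assembled genes. TRINITY_DN201416_c6_g1 stood at 1622 and TRINITY_DN205676_c17_g1 at 63.3 in the embryo library of tree 397. TRINITY_DN177757_c3_g6 stood at 5.49 in the embryo and 0.736 in the megagametophyte library of tree 251, and TRINITY_DN208987_c7_g1 at 0.677 in the needle library of that tree. In the phloem library of tree 485, TRINITY_DN193215_c3_g4 stood at 2.16 and TRINITY_DN187845_c9_g1 at 19.6. TRINITY_DN202005_c15_g1 stood at 0.540 in the phloem and TRINITY_DN191341_c3_g1 at 0.627 in the vegetative bud library of tree 397. TRINITY_DN178765_c1_g5 stood at 0.181 in the megagametophyte library of tree 485, and TRINITY_DN194839_c6_g5 at 0.870 in the vegetative bud library of tree 320.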

How the results depend on the processing

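Leaving out the 3 libraries with many assembled genes of their own, the other limits for the presence and absence pattern, and the paired tests of numbers per library were chosen after the data were seen. The named assembled genes kept their direction and stayed past the threshold under the other pseudocounts, filters and scalings, the tree block, robust eBayes and each fit with fewer libraries; the stricter log2, tau and detection limits were not applied to them. Of 369 alternative counts, 307 were within 1.5 times the count reported and 62 were not. Leaving out each tree in turn, robust eBayes, no filter, fitting the compared libraries alone, TPM without scaling and leaving out the 3 libraries moved no count that far. With tree as a replicate block, the preferential counts were 1699 in embryo, 1484 in megagametophyte, 5522 in needle, 3727 in phloem and 2645 in vegetative bud; 6882 assembled genes were higher in seed and 14793 in vegetative tissue, 6732 in embryo and 3893 in megagametophyte, 9493 in needle and 10569 in phloem, 9632 in needle and 11901 in vegetative bud, and 6930 in phloem and 7984 in vegetative bud. The block changed no call of a named assembled gene and moved no count by over 1.5 times. Paired sign-flip tests of the share of the needle total held by the 100 most abundant assembled genes had adjusted values of 0.125 in place of 0.0108. Needle was higher in 6 of 6 trees each time, and 6 trees allow no unadjusted p under 0.03125. The adjusted 0.125 therefore reflects that limit. Summing isoforms was not run because the identifiers are at gene level, and tests of gene lists were not run because there are no names. Depth is unknown, so what it limits cannot be stated.

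With a pseudocount of 5, preferential counts were 820 in embryo, 893 in megagametophyte, 2199 in phloem and 1426 in vegetative bud. The pairwise counts were then 2277 higher in seed and 5617 in vegetative tissue, 2823 in embryo and 1862 in megagametophyte, 5322 in needle and 5286 in phloem, 5556 in needle and 5400 in vegetative bud, and 3688 in phloem and 3472 in vegetative bud. With a pseudocount of 0.1, 12275 were higher in seed than in vegetative tissue, and 416 were specific to megagametophyte, 720 to phloem and 967 to vegetative bud. After quantile normalization 10177 were higher in seed. For the pseudocount and the normalization the cause was not tested. A filter of 5 in 6 libraries, which tests fewer assembled genes, gave 738 preferential in embryo, 715 in megagametophyte, 3136 in needle, 2156 in phloem and 1302 in vegetative bud. It also gave 3872 higher in seed, 5298 higher in needle than phloem, 5724 higher in needle than vegetative bud, 7112 higher in vegetative bud than needle, 4797 higher in vegetative bud than phloem, and 5138 with a tree effect.

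Stricter limits lower the counts by construction. A log2 difference of at least 2 gave 667 preferential in embryo, 652 in megagametophyte, 2825 in needle, 1545 in phloem and 1182 in vegetative bud. It gave 1440 higher in seed and 4614 in vegetative tissue, 2792 in embryo and 1517 in megagametophyte, 4823 in needle and 4518 in phloem, 4736 in needle and 5202 in vegetative bud, and 2774 in phloem and 3133 in vegetative bud. A tau of at least 0.95 gave 426 specific to embryo, 297 to megagametophyte, 1289 to needle, 378 to phloem and 606 to vegetative bud. A value of at least 1 in all 6 libraries gave 559 specific to embryo and 360 to megagametophyte. Detection at 0.1 gave 55515 in embryo, 47057 in megagametophyte, 55742 in needle, 51526 in phloem and 67320 in vegetative bud, and detection at 5 gave 12172, 10351, 13865, 14744 and 15142.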

Other observations

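The counts by number of trees and the alternative limits in the first paragraph were chosen after the result was seen, and the splits of libraries were set before their results were known.

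Of the 425 assembled genes present in the vegetative tissues of some trees and absent from those of others, 227 were present in 1 tree. There were 79 in 2 trees, 46 in 3, 40 in 4 and 33 in 5. Presence needed at least 5 scaled TPM in all 3 libraries of a tree and absence under 0.1, so the rule shapes these counts. Where the mother tree lacked them, the share reaching 1 in the embryo was 5.64% for those present in 1 tree, 19.6% for 2, 26.1% for 3, 41.3% for 4 and 42.4% for 5. In the megagametophyte the shares were 1.41%, 4.75%, 10.9%, 7.50% and 21.2%. Where the mother tree had them, the megagametophyte shares were 61.2%, 62.0%, 63.8%, 54.4% and 59.4%, and the embryo shares 62.6%, 68.4%, 70.3%, 68.8% and 80.6%. Where the mother lacked them, the shares were thus higher for 5 trees than for 1 in both seed tissues. The excess of embryo over megagametophyte where the mother lacked them was 7.70 percentage points with presence set at 10, 9.01 with absence at exactly 0, and 9.37 with a seed limit of 5, with embryo higher in 6 of 6 trees each time. Where the mother had them, embryo and megagametophyte shares were 71.1% and 60.6%, 70.1% and 61.0%, and 59.1% and 54.4% in that order of settings.

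No other assignment tried gave as many calls for the preferential counts, seed against vegetative tissue, the 10 tissue pairs or the tree effect. Shuffling puts real differences between tissues or trees into the spread of the fit. The low counts of other assignments are therefore no rate of false calls. In 100 assignments of the 30 libraries to tissues, 1, the real one, gave as many preferential assembled genes; the highest other count was 0 for embryo and 1 for each of the other 4 tissues, against 1490, 1360, 5314, 3515 and 2544. With tissues exchanged within trees, the highest other counts were 284 for embryo, 1 for megagametophyte, 2282 for needle, 0 for phloem and 2 for vegetative bud. Seed against vegetative tissue gave 21094 calls, and at most 3504 in other assignments (603 within trees). For the pairs of a seed and a vegetative tissue, the calls and the highest other counts were 24015 and 672 for embryo against needle, 23381 and 3943 for embryo against phloem, 16660 and 3 for embryo against vegetative bud, 21761 and 259 for megagametophyte against needle, 21585 and 8 for megagametophyte against phloem, and 19820 and 1 for megagametophyte against vegetative bud. Within trees the highest others were 6638, 7157, 2118, 7497, 3650 and 1798. In 100 splits of 12 libraries, embryo against megagametophyte gave 9585 and at most 4406 otherwise, needle against phloem 18776 and 10671, needle against vegetative bud 20246 and 11119, and phloem against vegetative bud 14009 and 7664. The 32 splits that part every tree's pair gave at most 3896, 10450, 10642 and 6950 besides the real one. Both kinds of split can keep most libraries under their real tissue, as where the tissues of a single tree are exchanged. These high counts are therefore no level expected without a difference. The tree effect gave 9902, and at most 564 with trees shuffled within tissues.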
